A study of Homo sapiens with 4 samples.

How the data were processed

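The series holds 4 Affymetrix expression arrays of human bone marrow mesenchymal stem cells, 1 for each of 4 groups: control, FGF2, scrambled siRNA and TWIST1 siRNA. Samples were placed in groups by their titles in the labels. The RNA on each array was a pool of 3 RNA extractions, per the series design text; whether these came from separate cultures or donors, and the array model, are not given in the sources used here. The deposited values are linear intensities rounded to whole numbers, which the authors processed with Affymetrix Expression Console, per the submitters' processing notes. The name of their table calls them normalized. The normalization method, the background correction and the way probes were summarised are not given in the sources used here. If the normalization was done between arrays, it would remove a shift shared by most genes. Differences would then be relative to the typical gene of each array.

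Both deposited tables held the same intensities (100% of values equal), and 1 of them also held annotation columns. Each of the 21427 probe sets in them reached 100 on at least 1 array, so the authors' table had a lower limit of 100 for the brightest array. Of these probe sets 14692 carried 1 gene symbol, 6460 none, 195 several, 15 a date in place of a symbol, and 65 were control probe sets. Genome positions are those of the deposited annotation, on GRCh37 as 4743 of its transcript descriptions state, and 713 probe sets lay on alternative haplotype sequences. A further 4 columns, headed as a logical test or not at all, matched no sample by name and were not used.

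Analyses used probe sets with 1 symbol. For the 593 genes with more than 1 probe set the brightest was used, giving 13397 genes, and log2 of the intensity was taken with no offset, since no value was 0 or below. Array medians over all probe sets ranged from 197 to 207, and from 87.2% to 89.2% of probe sets read above 100 on each array. With 1 array per group the number of arrays limits the precision, and no test between groups was possible. A rule of size was used: a log2 difference of at least 1, with the brighter array at or above the median log2 value of all genes, 7.79 or an intensity of 222. For values under 100, the lower limit of the table, folds are given as "at least", with 100 as the dimmer value.

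The groups, the comparisons, the rule of size, the gene lists, the rule for named genes and most alternatives were set before the data were examined. The comparisons were FGF2 over control, TWIST1 siRNA over scrambled siRNA and scrambled siRNA over control. The overlap of the first pair was set beside n1 × n2 / N. This is the number that independent lists drawn from all N measured genes would share, and it ignores the floor. TWIST1 was always reported. In each comparison the text draws on the 10 genes with the largest difference in each direction among those past the rule of size, leaving out probe sets with several or no symbols, symbols of small RNAs and unnamed loci, XIST and Y-linked genes. It also draws on up to 4 members per gene list with the largest absolute difference, and on up to 5 genes per pair of directions for the overlap. Genes named outside the rule are said to be so. Some genes that the rule selects are not reported here.

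Gene lists were FGF-ERK feedback and target genes, FGF ligands and receptors, immediate early genes, DNA replication and G1/S genes, mitosis and G2/M genes, p53 targets and CDK inhibitors, MSC surface markers, Twist, Snail and Zeb factors with cadherins, osteogenic, adipogenic and chondrogenic genes, smooth muscle and contractile genes, extracellular matrix genes, matrix proteases and inhibitors, angiogenic factors, and immunomodulatory factors. They were also NF-kB targets and chemokines, interferon-stimulated genes, antigen presentation genes, TGF-beta targets, BMP pathway, ID and HES genes, WNT pathway genes, cholesterol synthesis and SREBP2 targets, hypoxia and glycolysis genes, ATF4 and unfolded protein response genes, NRF2 and antioxidant genes, ribosomal protein genes, mitochondrially encoded genes, and blood cell, endothelial and epithelial markers. Of 636 fixed members of the 31 lists 464 were measured, and 30 lists had at least 3 measured members. Each list's median log2 difference was set against 10000 random lists of the same size, drawn from genes matched in 20 bins of mean expression, and called outside the range when it fell beyond their central 95%. These percentiles describe these arrays and are not p-values. The lists share some members, and lists of fewer genes have wider ranges. Histone and lysosomal lists were added after the leading genes had been seen.

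Alternatives were 1.5-fold and 3-fold in place of 2-fold, no floor or a floor at the upper quartile (intensity 444), each array minus its median, quantile normalization, removal of the trend of the difference with mean intensity (lowess, span 0.3), the mean of all probe sets of a gene, the other deposited table, list members at or above the floor only, and the other control array. The procedures were tested on simulated data made from the 13397 genes with normal noise of the spread seen in each comparison and 50 genes changed at each fold. The changed genes were drawn only from those at or above the floor on the array named second in the comparison. The shares called below thus hold for such genes and not for all measured genes. For FGF2 over control 46% of simulated 2-fold and 100% of 3-fold genes were called, for TWIST1 siRNA over scrambled siRNA 58% and 94%, and for scrambled siRNA over control 50% and 100%. Of 13197 unchanged genes 0 were called for FGF2 over control, 138 (1.05%) for TWIST1 siRNA over scrambled siRNA, whose wider spread also holds any real differences, and 0 for scrambled siRNA over control. Normal noise of the smaller spreads hardly reaches a log2 difference of 1, so the counts of 0 are no estimate of false calls. Of 100 unchanged lists 3, 6 and 5 fell outside the range in these comparisons. These lists were random genes with independent noise, so the range itself largely sets these numbers. They say nothing on how often a list of genes that vary together falls outside. Probe sets with no or several symbols were left out of the gene counts, and single genes in families of near-identical copies are reported as uncertain. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.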

Results

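Gene expression was measured on 4 Affymetrix arrays in human bone marrow mesenchymal stem cells (MSCs), adherent stromal cells that can form bone, fat and cartilage, at passage 2 and before confluence. The 4 groups had 1 array each: growth medium alone (control), growth medium with fibroblast growth factor 2 (FGF2) at 20 ng/ml for 24 h, a scrambled small interfering RNA (siRNA) for 3 days, and an siRNA against TWIST1 for 3 days. Each array was hybridized with a pool of 3 separately extracted RNA samples. There were no replicates, so the differences had no replicate check, no p-value was computed, and the number of arrays limits the precision of each value. The values were normalized intensities made by the authors, and 13397 genes were measured. A gene was called higher or lower where its log2 difference between 2 arrays was at least 1, a 2-fold difference, and the brighter of the 2 arrays read at least 222, the median of all genes. Positions are on GRCh37.

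TWIST1, the basic helix-loop-helix transcription factor targeted by the siRNA, read 245 on the control array, 187 on the FGF2 array, 242 on the scrambled siRNA array and 181 on the TWIST1 siRNA array. Its log2 difference was -0.42 for TWIST1 siRNA over scrambled siRNA, -0.39 for FGF2 over control and -0.02 for scrambled siRNA over control. TWIST1 was thus lower on the array labelled with its siRNA, and lower by a similar amount on the FGF2 array, and neither difference reached 2-fold. TWIST2, the closest relative of TWIST1, read 152 on the control array and 232 on the FGF2 array, a log2 difference of 0.61. TWIST1 was read by probe set 17055614, whose annotated interval on chromosome 7 runs from 19039116 to 19157295 on the minus strand. That interval of 118180 bp is much longer than the TWIST1 gene. All 4 TWIST1 readings lay within the range of 103 to 420 covered by 8 background control probe sets, as did the readings of 48.2% of all genes.

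The TWIST1 siRNA array stood apart from the other 3. Across genes, which are not independent replicates, Pearson's r was 0.981 between control and FGF2, 0.982 between control and scrambled siRNA, and 0.976 between FGF2 and scrambled siRNA. It was 0.916 between scrambled siRNA and TWIST1 siRNA, 0.914 between control and TWIST1 siRNA, and 0.898 between FGF2 and TWIST1 siRNA. The array medians were close, at 207 for control, 204 for FGF2, 203 for scrambled siRNA and 197 for TWIST1 siRNA. The poly-A and ERCC control RNAs split the arrays another way. The 12 poly-A spike-in probe sets were 3.22 times brighter on the control array than on the FGF2 array, and 3.48 times brighter on the TWIST1 siRNA array than on the scrambled siRNA array. Their ratio was 1.01 for TWIST1 siRNA over control and 1.07 for FGF2 over scrambled siRNA. The 3 ERCC spike-in probe sets split the same way, with ratios of 2.99 for control over FGF2 and 3.23 for TWIST1 siRNA over scrambled siRNA. Other control probe sets did not follow this split: on the TWIST1 siRNA array all 9 hybridization controls were brighter than on the scrambled siRNA array, by 1.39 to 1.67 times with a ratio of means of 1.51, and so were all 8 background control probe sets, by 1.08 to 1.37 times with one of 1.24. Over control these ratios of means were 1.40 and 1.16, but the hybridization controls then ranged from 0.957 to 11.5, the first below 1 and the last from a probe set that read 44 on the control array, so the 1.40 is not shared by all of them.

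**Figure D1:**
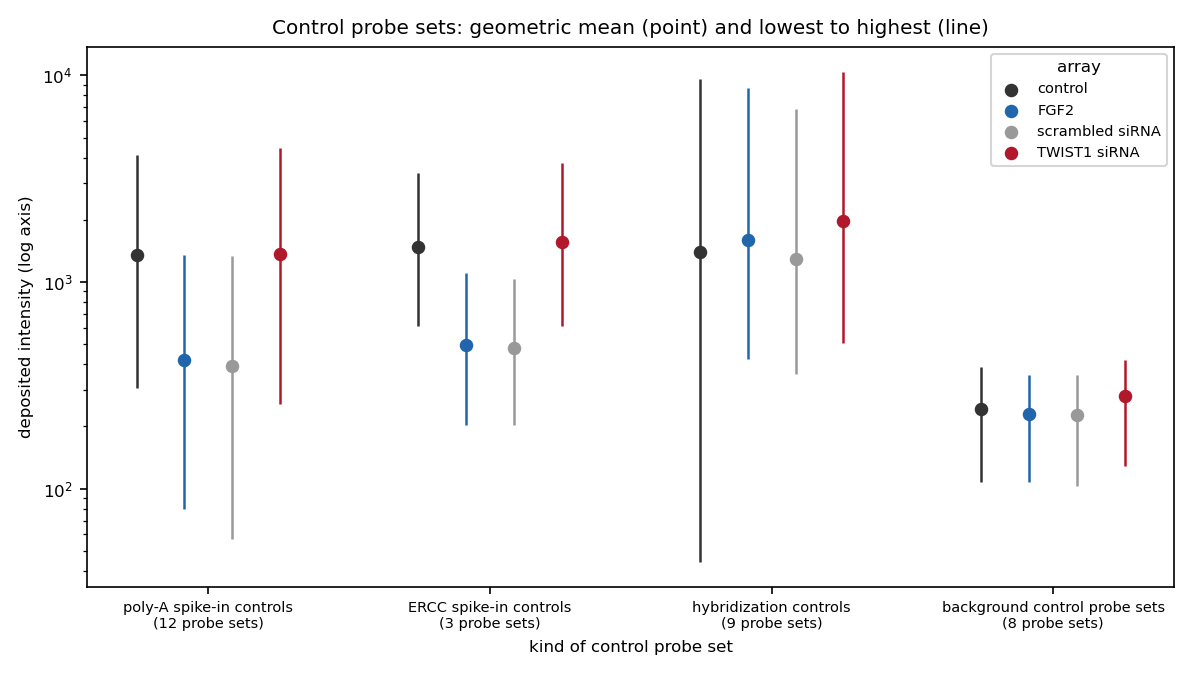
Deposited intensity (log axis) of 4 kinds of control probe set on each of the 4 arrays, where a point is the geometric mean of the probe sets and a line runs from the lowest to the highest. The poly-A spike-in mean was 1352 on the control array and 1371 on the TWIST1 siRNA array, but 420 on the FGF2 array and 394 on the scrambled siRNA array, while the background control probe sets ranged only from a mean of 226 to one of 280.

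The first comparison set FGF2 against control, to describe how the cells respond to a growth factor that the study used to alter TWIST1 expression and function. On the FGF2 array 24 genes were at least 2-fold higher and 21 at least 2-fold lower. ITGA2, the alpha 2 chain of a collagen-binding integrin, was higher by a log2 difference of 2.30 (999 against 203). MMP1, the interstitial collagenase, was higher by 2.13 (4841 against 1103), ESM1, a secreted proteoglycan, by 1.92 (1634 against 432) and STC1, a secreted glycoprotein, by 1.79 (726 against 210). Among the genes that were lower, PDGFRB, a receptor for platelet-derived growth factor, differed by -1.32 (312 against 779), COL4A1, a basement membrane collagen, by -1.24 (245 against 578) and PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, by -1.18 (595 against 1347).

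The other leading genes that were higher on the FGF2 array were PITPNC1 at 1.35, STEAP1 at 1.30 and HIST1H3J, a replication-dependent histone gene with near-identical copies whose value is thus uncertain, at 1.26. DSCAM-IT1 and PTPN22 read below 100 on the control array and were at least 2.53-fold and at least 2.78-fold higher on the FGF2 array. PTMA was higher by 1.92 on 3 probe sets with identical values, and the one used is annotated on chromosome 12 from 12264886 to 12264970. PTMA has near-identical processed copies, so this value is uncertain and may not be that of the PTMA gene itself. Its other probe set, dim at 119 or less on each array, differed by only 0.06. The leading genes that were lower also included FNDC1 at -1.57, the immediate early transcription factor EGR1 at -1.42 and the receptor phosphatase PTPRQ at -1.33. For scrambled siRNA over control EGR1 differed by 0.30, but PTPRQ by -1.05. CHST3, a chondroitin sulfotransferase, differed by -1.22, EPAS1, a hypoxia-inducible factor, by -1.19 and IGFBP3, a binding protein of insulin-like growth factors, by -1.17. ITGA2 lies on chromosome 5 from 52285156 to 52390609 (probe set 16984689), MMP1 on chromosome 11 from 102660641 to 102668966 (probe set 16743721) and PDGFRB on chromosome 5 from 149493400 to 149535435 (probe set 17001578). When the scrambled siRNA array took the place of the control array, 14 of the 24 higher genes and 11 of the 21 lower genes were called again. ITGA2 then differed by 1.35 and PTMA by 0.43, while MMP1 differed by 2.69 and ESM1 by 2.58.

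Genes of the FGF and ERK pathway were higher as a group on the FGF2 array. Of its 20 measured members 13 were above 0, the median was 0.18, and this exceeded the medians of all 10000 random lists of matched expression. SPRY2 and SPRED1, feedback inhibitors of the pathway, differed by 0.79 and 0.63, and HMGA2, a chromatin protein, by 0.55, whereas EGR1 went the other way. Matrix proteases and their inhibitors had a median of 0.08 at percentile 98.6 of the random lists, a call that ended with the intensity trend removed and over members bright enough for the rule, with MMP1 and STC1 as the 2 members called higher. MMP16 differed by 0.67 in this list and the gelatinase MMP2 by -0.62. For scrambled siRNA over control MMP16 differed by a like 0.74 and MMP1 by -0.56.

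Osteogenic, contractile and matrix genes were lower as groups on the FGF2 array, next to the lower spike-in level of this array. The osteogenic list had a median of -0.33 with 9 of 12 members below 0, among them the type I collagen genes COL1A1 at -1.07 and COL1A2 at -0.82 and the bone transcription factor DLX5 at -0.50. The smooth muscle and contractile list had a median of -0.45 with 11 of 14 members below 0, including CNN1 at -0.69, TAGLN at -0.65 and ACTA2 at -0.50. For scrambled siRNA over control CNN1 differed by a like -0.72 and ACTA2 by -0.36. In the extracellular matrix list 23 of 26 members were below 0 and the median was -0.29, with COL4A2 at -0.96, COL3A1 at -0.91 and COL5A1 at -0.73. Target genes of transforming growth factor beta (TGF-beta) had a median of -0.36 with 13 of 15 members below 0, including CTGF at -0.60 and TGFBI at -0.60. The other, dimmer probe set of CTGF differed by -0.22. Genes of the BMP pathway with the ID and HES genes had a median of -0.36 with 13 of 15 below 0, including INHBA at -0.69, SMAD6 at -0.63 and BAMBI at -0.62. These 5 medians lay below those of all 10000 random lists. On the spike-in-matched pair, FGF2 over scrambled siRNA, each stayed below the central 95% of random lists, at -0.48 for osteogenic, -0.47 for BMP, -0.25 for TGF-beta, -0.18 for matrix and -0.13 for contractile genes.

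Smaller group differences on the FGF2 array were a median of -0.27 for FGF ligands and receptors, with FGF2 itself at -0.34, and -0.27 for chondrogenic genes, with HAPLN1, a link protein of cartilage matrix, at -0.93 and SOX9, a chondrogenic transcription factor, at 0.46. For scrambled siRNA over control HAPLN1 differed by a like -0.85 and SOX9 by 0.04. The chondrogenic median turned to 0.15 over the 3 members bright enough for the rule. Genes of cholesterol synthesis had a median of -0.19, with the fatty acid desaturase SCD at -0.70 and DHCR7 at -0.54. MSC surface markers had a median of -0.18, where ITGA11 differed by -0.71, ENG by -0.45 and CD63 by 0.46, and immediate early genes one of -0.17, where FOSL2 differed by -0.91, DUSP1 by -0.42 and JUN by 0.34. Against the scrambled siRNA array the calls of the FGF ligand, chondrogenic, MSC surface, immediate early and protease lists ended, and 7 of the 12 calls held. The cell cycle lists lay within the range of random lists on the FGF2 array, at 0.02 for mitosis and G2/M genes and 0.03 for DNA replication and G1/S genes, although against the scrambled siRNA array they lay above it at 0.21 and 0.22. The other 16 lists lay within the range, from -0.18 for epithelial markers to 0.15 for endothelial markers. Against the scrambled siRNA array 7 of these 16 lay outside it: p53 targets at -0.15, adipogenic genes at -0.21, angiogenic factors at -0.18, NF-kB targets at -0.20, antigen presentation genes at -0.14 and ATF4 genes at -0.13 below, and endothelial markers at 0.38 above, so that 16 lists in all lay outside in place of 12. Over the control array, the lists within the range included the Twist, Snail and Zeb factors with cadherins at -0.11, where the cadherin CDH11 differed by -0.59. They also included p53 targets, at -0.12 over control, where CDKN1A differed by -0.32.

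**Figure D2:**
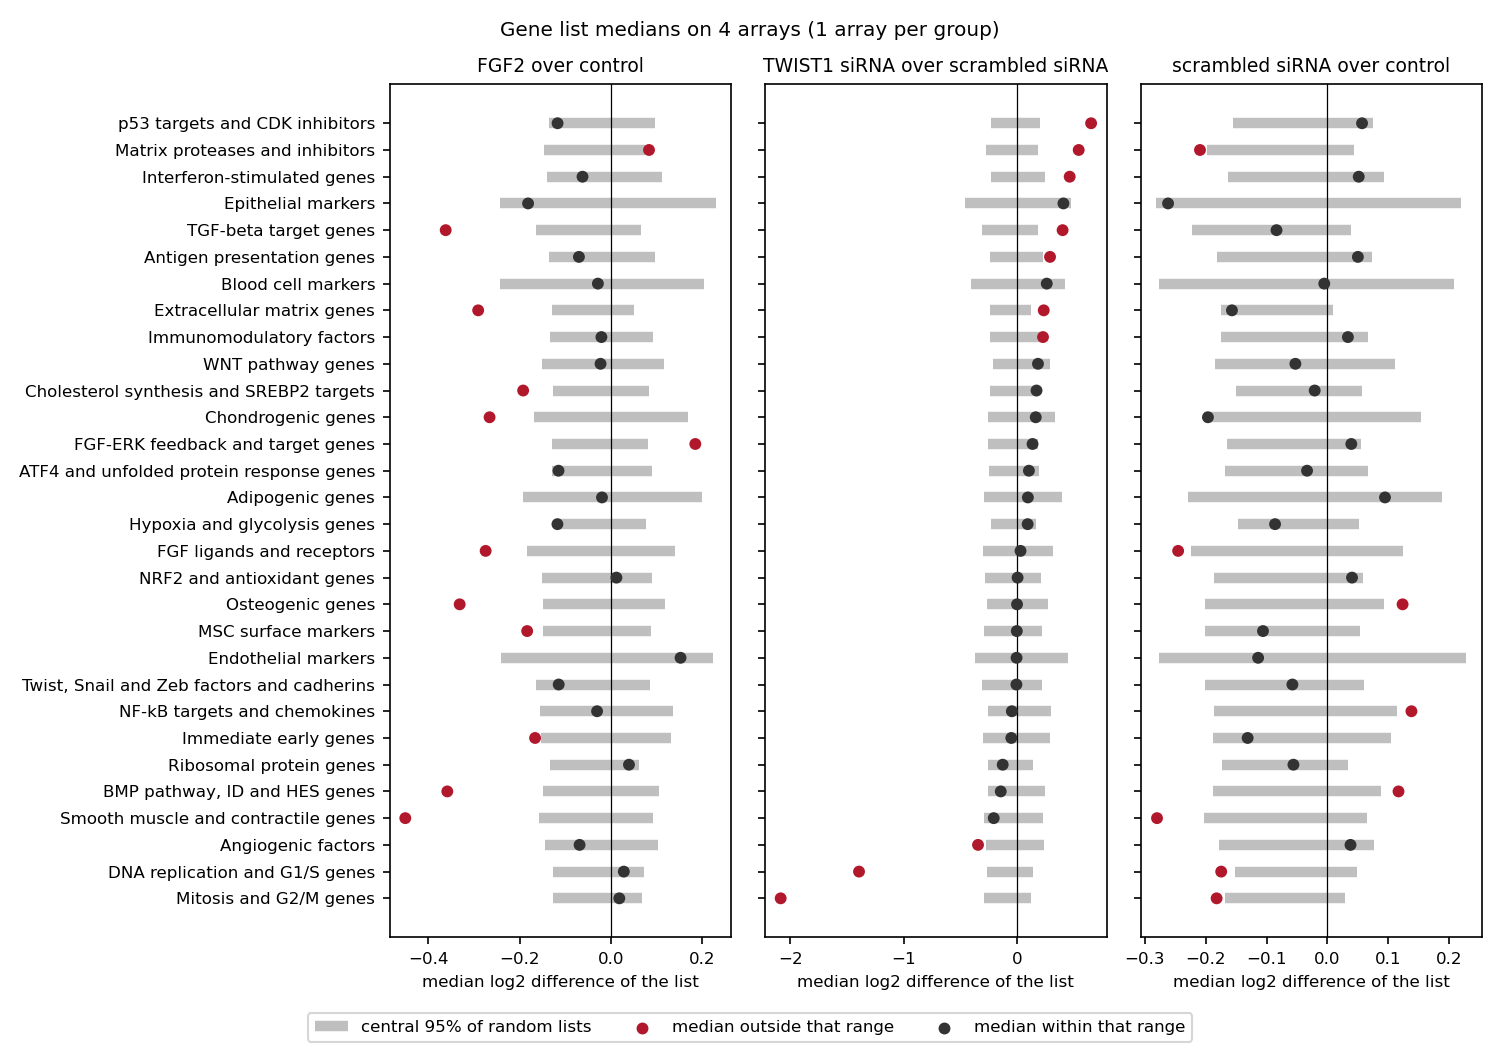
Median log2 difference of each of 30 gene lists (points) in 3 comparisons of 1 array with 1 array, with the central 95% of 10000 random lists of matched expression (grey bars). Red points lie outside the bar: 12 lists for FGF2 over control, 10 for TWIST1 siRNA over scrambled siRNA, where mitosis and G2/M genes reached -2.08, and 8 for scrambled siRNA over control. The 3 panels have different axes.

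The comparison of TWIST1 siRNA with scrambled siRNA asked which genes differ when TWIST1 is targeted. Here 132 genes were at least 2-fold higher and 405 at least 2-fold lower on the TWIST1 siRNA array. Genes of cell division were lower: all 25 mitosis and G2/M genes of the list were at least 2-fold lower, and their median was -2.08, below all 10000 random lists. TOP2A, the topoisomerase of mitotic chromosomes, differed by -2.39, the mitotic kinase PLK1 by -2.36 and the kinetochore motor CENPE by -2.32, while NDC80, a kinetochore protein, read 88 against 471 and was at least 4.71-fold lower. Of the 24 DNA replication and G1/S genes 16 were called lower and all were below 0, with a median of -1.39. Among them were the thymidylate synthase TYMS at -2.28 and the origin licensing factor CDC6, which read 98 against 477 and was at least 4.77-fold lower. On the higher side, HMOX1, the inducible heme oxygenase, had the largest difference, 3.33 (3017 against 299).

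In the replication list DTL differed by -2.09, and MCM10, a replication factor, read 90 against 390 and was at least 3.90-fold lower. The leading lower genes outside the lists included the kinetochore genes NUF2 at -2.63, SKA3 at -2.61 and CASC5 at -2.44, the kinase gene PBK at -2.60 and SHCBP1 at -2.53. KIF14, a kinesin, and CDCA2 read below 100 on the TWIST1 siRNA array and were at least 4.45-fold and at least 5.10-fold lower there. The histone genes HIST1H1B, which was at least 6.70-fold lower, HIST1H2AI at -2.90 and HIST1H4L at -2.51 belong to a family of near-identical copies, so their single values are uncertain. NUF2 lies on chromosome 1 from 163236366 to 163325554 (probe set 16673154) and HMOX1 on chromosome 22 from 35776354 to 35790207 (probe set 16929562). When the untransfected control array took the place of the scrambled siRNA array, 353 of the 405 lower genes and 76 of the 132 higher genes were called again, and the mitosis median was -2.33. That pair of arrays had matched poly-A and ERCC levels.

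**Figure D3:**
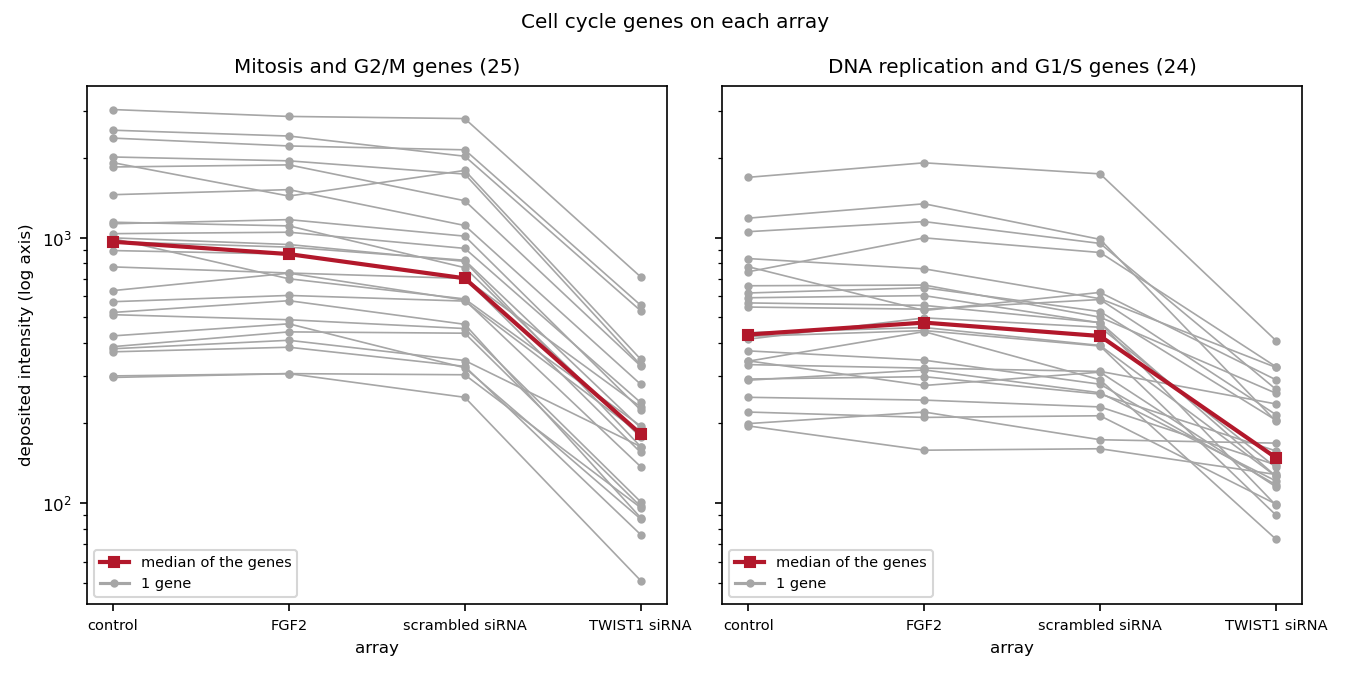
Deposited intensity (log axis) of 25 mitosis and G2/M genes (left) and 24 DNA replication and G1/S genes (right) on the 4 arrays. Each grey line joins the values of 1 gene and the red squares are medians, and in both panels the median was lowest on the TWIST1 siRNA array, with log2 medians of -2.08 and -1.39 against the scrambled siRNA array.

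Targets of p53 and inhibitors of cyclin-dependent kinases were higher as a group on the TWIST1 siRNA array. Of 19 measured members 16 were above 0 and 4 were called higher, and the median was 0.65, above all random lists. CDKN1A, the p21 inhibitor of cell cycle kinases, read 676 against 337, while BTG2, an antiproliferative gene, differed by 1.19 and TNFRSF10B, a death receptor, by 1.03. GDF15, a secreted member of the TGF-beta family, differed by 2.52 on its brightest probe set (1500 against 261), while its other 2 probe sets, at 117 or less on each array, were too dim to be informative. Other leading genes that were higher were TXNIP, the thioredoxin-interacting protein, at 2.35, the lysosomal fucosidase FUCA1 at 2.12, the circadian transcription factor DBP at 2.01, the efflux transporter ABCC3 at 1.83 and SPATA18 at 1.61. The ubiquitin ligases FBXO32 and PARK2 read below 100 on the scrambled siRNA array and were at least 2.34-fold and at least 2.27-fold higher on the TWIST1 siRNA array.

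Interferon-stimulated genes had a median of 0.46 with 15 of 16 members above 0, including IFI6 at 1.87, IFI44L at 1.02 and the signalling factor STAT2 at 0.99. Antigen presentation genes had a median of 0.29 with 13 of 16 above 0, including the class I genes HLA-E at 0.88 and HLA-C at 0.78 on their brightest probe sets. Over all their probe sets HLA-E ranged from 0.55 to 0.88 and HLA-C from 0.44 to 0.78, so the single values are uncertain. Matrix proteases and inhibitors had a median of 0.54, with the membrane-bound protease MMP14 at 1.03 and the plasminogen activator PLAT at 0.93, while MMP1 differed by -1.22. That protease median was 0.21 against the untransfected control, where PLAT turned to -0.10 (824 against 885), its scrambled siRNA value of 431 being low. TGF-beta targets had a median of 0.40 with 14 of 15 above 0, including LTBP1 at 0.92 and ITGB5 at 0.87. Extracellular matrix genes had a median of 0.23 with 19 of 26 above 0, including the proteoglycan LUM at 1.16, FBLN5 at 1.10 and COL3A1 at 0.65. Against the untransfected control LUM differed by 0.60 and FBLN5 by 0.37, and no member of this list was called. Immunomodulatory factors had a median of 0.23, with HMOX1 and PTGES, a prostaglandin E synthase at 1.13, called higher and the checkpoint ligand CD274, at -1.16, called lower; this call ended with each array minus its median, with the trend removed and over members bright enough for the rule. All 10 lists outside the range of random lists lay on the same side of it when the untransfected control array was used.

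Angiogenic factors were lower as a group, with a median of -0.35 and 13 of 17 members below 0, although ANGPTL2 at 1.18 and ANGPTL4 at 1.08 were called higher and KITLG, the ligand of the KIT receptor, at -1.10 lower. Against the untransfected control their median was -0.57, with 10 members below 0 and 7 above, and 2 called each way, while over members bright enough for the rule the median against scrambled siRNA was -0.23, within the range. The contractile list had a median of -0.21 within the range of random lists, with CALD1 at -0.90 and ACTA2 at -0.82, and -0.59 below the range against the untransfected control. Cholesterol synthesis genes lay just inside the range, with a median of 0.17 at percentile 97.4, and the sterol-regulated genes INSIG1 at 1.29 and SCD at 1.13 were among the members called higher. Against the untransfected control that median was 0.05 at percentile 88.2, and 1 member was called higher in place of 3. The osteogenic median was -0.0027, with COL1A1 at 0.60, and COL1A2 differed by 0.54 on its brightest probe set but by 0.04 and 0.07 on the others. The FGF and ERK list had a median of 0.13, with the transcription factor ETV1 at 1.31 and the ERK phosphatase DUSP6 at 0.95 against EGR1 at -1.70. The BMP list had a median of -0.15, although BMP4, a ligand of the pathway, read 284 against 94 and was at least 2.84-fold higher. The Twist, Snail and Zeb list had a median of -0.01, with TCF4, which encodes an E protein, at 0.87, SNAI2 at -0.48 and ZEB1 at -0.45. The chondrogenic median of 0.16 became 0.74, above the range, over the 3 members bright enough for the rule, of which SOX9 differed by 0.86.

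The remaining lists lay within the range of random lists on the TWIST1 siRNA array. Their medians were 0.03 for FGF ligands and receptors, where FGF5 read 1231 against 2468, -0.05 for immediate early genes and -0.05 for NF-kB targets and chemokines, where the chemokine CCL2 was called lower at -1.71. MSC surface markers had a median of -0.0049, with ITGA11 at 0.99 and NT5E, the ecto-nucleotidase CD73, at 0.61. The medians were 0.18 for WNT pathway genes, where the WNT inhibitor DKK1 differed by 0.61, 0.09 for hypoxia and glycolysis genes, 0.10 for ATF4 and unfolded protein response genes, 0.0021 for NRF2 and antioxidant genes and -0.13 for ribosomal protein genes. Adipogenic genes had a median of 0.09 over 6 measured members. Markers of other cell types that bone marrow cultures could hold had medians of 0.26 for 4 blood cell genes, where CD68 differed by 1.04, -0.01 for 4 endothelial genes and 0.41 for 5 epithelial genes. Only 2, 0 and 2 of these genes were bright enough for the rule, so the medians say little on cell content. CD68 was bright on every array, from 1176 to 2418. None of the 13 mitochondrially encoded genes fixed as a list was matched by symbol.

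The scrambled siRNA array was set against the control array to describe what transfection without a TWIST1 target altered. Only 4 genes were at least 2-fold higher and 13 at least 2-fold lower on the scrambled siRNA array. SEMA3A, a secreted guidance factor, was higher by 1.22, PARP14, an interferon-inducible ADP-ribosyltransferase, by 1.02, and PTMA, with the same uncertain copies, by 1.49. The dim other probe set of PTMA differed by 0.21. The fourth gene, FLJ22447, read 467 against 199 and was named after its values were seen. The leading lower genes were DOK5, a docking protein, at -1.43, the microfibril gene MFAP5 at -1.33, the keratin gene KRT34 at -1.15, IGFBP5 at -1.11 and PLAT at -1.04. RAVER2 differed by -1.08, NFASC by -1.05, PTPRQ by -1.05, and MOXD1 by -1.03, while the amino acid transporter SLC1A4 read 202 against 405. The split of 4 higher and 13 lower genes became 5 and 7 after quantile normalization and 5 and 8 with the intensity trend removed. These arrays differed in spike-in level, with the poly-A probe sets 3.43 times brighter on the control array.

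Contractile genes were lower as a group on the scrambled siRNA array, with a median of -0.28 and CNN1 at -0.72. The FGF ligands and receptors had a median of -0.25, with FGF2 at -0.39, the matrix proteases and inhibitors -0.21, mitosis and G2/M genes -0.18, with CDC20, an activator of the anaphase-promoting complex, at -0.76, and DNA replication and G1/S genes -0.17, with UHRF1 at -0.50. Above the range of random lists were NF-kB targets and chemokines at 0.14, with IL7R at 0.72, osteogenic genes at 0.12, with RUNX2, the bone master regulator, at 0.34, and the BMP list at 0.12, with the activin antagonist FST at 0.39. Interferon-stimulated genes had a median of 0.05 within the range, where IFI44 differed by 0.60. Of these 8 lists, the contractile, protease, mitosis and BMP lists, 4 in all, lay outside the range when only members bright enough for the rule were used. The protease and BMP calls ended with the intensity trend removed, and the protease call also with the mean of all probe sets.

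The FGF2 and TWIST1 siRNA comparisons share no array, and were set side by side because both treatments were meant to act on TWIST1. Their spike-in differences go opposite ways, with poly-A ratios of 0.311 for FGF2 over control and 3.48 for TWIST1 siRNA over scrambled siRNA. A total of 10 genes reached 2-fold in both. EGR1 was lower in both, at -1.42 and -1.70, as were PTPRQ at -1.33 and -1.30 and the cation channel gene TRPC4, which read 139 against 278 and 106 against 304. PTPRQ also differed by -1.05 for scrambled siRNA over control, and it was not shared with the control arrays exchanged. MMP1 was higher on the FGF2 array, at 2.13, and lower on the TWIST1 siRNA array, at -1.22, and so were PTMA and HIST1H2AI, both with near-identical copies. The dim other probe set of PTMA differed by 0.06 and 0.22 in these comparisons. FNDC1 went from lower with FGF2, at -1.57, to higher with TWIST1 siRNA, at 1.12. It read 545 on the control, 184 on the FGF2, 305 on the scrambled siRNA and 665 on the TWIST1 siRNA array. These values follow the spike-in levels, and FNDC1 was not shared with the control arrays exchanged. KIAA1199 and RN5S26, lower in both, and MIR31, higher in both, complete the 10 and were named after their values were seen.

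Independent lists of these sizes would share 0.635 genes that were lower in both comparisons, where 5 were observed, and 0.236 that were higher in both, where 1 was observed. They would share 0.726 higher with FGF2 and lower with TWIST1 siRNA, where 3 were observed, and 0.207 the other way, where 1 was observed. With the control arrays exchanged, the shared genes numbered 8, of which 3 were lower in both, 4 higher with FGF2 and lower with TWIST1 siRNA, 1 higher in both and 0 the other way, and EGR1, MMP1, TRPC4 and RN5S26 were again among them. At 1.5-fold the largest group was lower with FGF2 and higher with TWIST1 siRNA, 26 genes where independent lists would share 6.81, followed by 19 lower in both (11.9), 14 higher with FGF2 and lower with TWIST1 siRNA (6.85) and 7 higher in both (3.93). Which directions were shared most thus depended on the limit and the control array. The expected numbers count all 13397 genes. Only 7140 genes were bright enough to be called for FGF2 over control, and 7387 for TWIST1 siRNA over scrambled siRNA. The expected numbers are thus too low, and an excess over them is no measure of a link between the comparisons. Across all genes the differences of the 2 comparisons had a Pearson's r of -0.098 and a Spearman's rho of -0.114, and of -0.198 and -0.185 with the control arrays exchanged. Over the 7746 genes at or above the floor on at least 1 array these were -0.167 and -0.206, and -0.248 and -0.252 with the exchange.

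**Figure D4:**
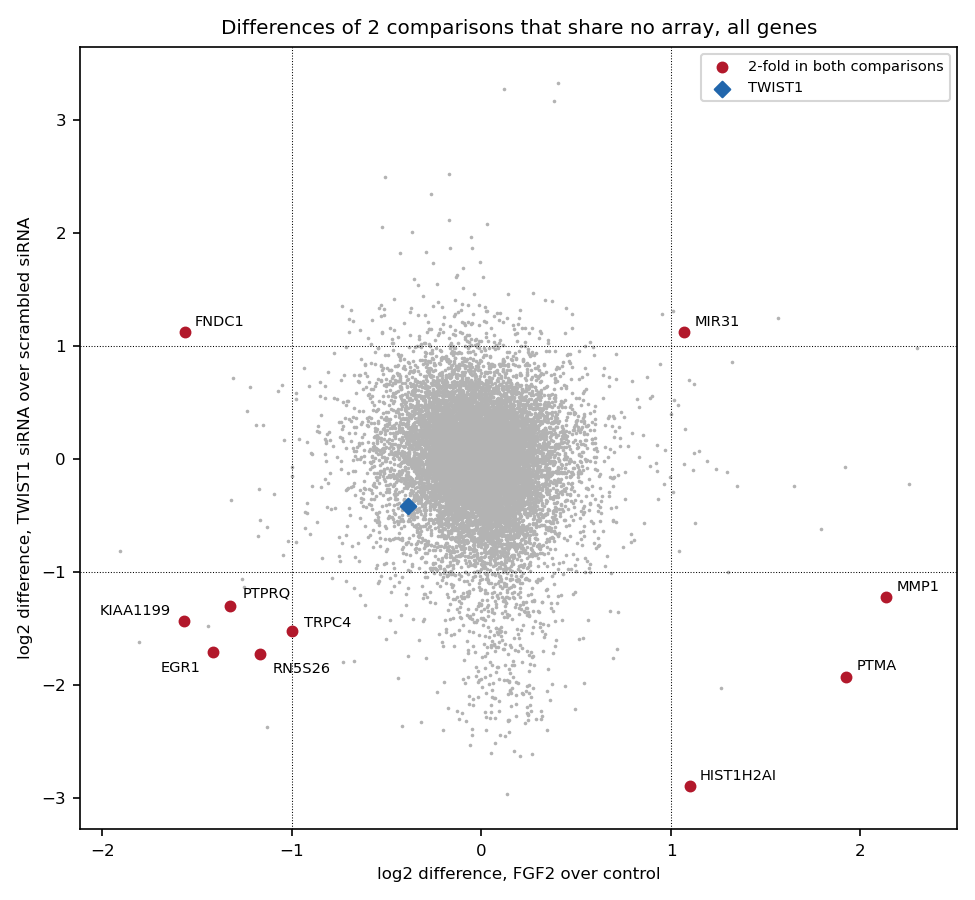
Log2 difference of each of 13397 genes for FGF2 over control (horizontal axis) and TWIST1 siRNA over scrambled siRNA (vertical axis), where dotted lines mark a 2-fold difference and red points are the 10 genes called in both. The blue diamond is TWIST1, at -0.39 and -0.42, and the grey points beyond both lines were too dim for the rule in at least 1 of the comparisons.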

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

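All tests of the 3 patterns weighed here were chosen after the results were seen, and so was the search among control and unnamed probe sets.

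Signals appeared among probe sets that carry no gene symbol. By the rule of size, 37 of them were higher and 19 lower on the FGF2 array than on the control array. On the TWIST1 siRNA array 73 were higher and 222 lower than on the scrambled siRNA array. On the scrambled siRNA array 59 were higher and 30 lower than on the control array. The probe set with the largest difference, 16867222, which comes with no position or transcript, read 160 on the control array, 3741 on the FGF2 array, 2547 on the scrambled siRNA array and 3379 on the TWIST1 siRNA array, which does not follow the spike-in levels. The poly-A spike-in controls, which no comparison of genes uses, were brighter on the TWIST1 siRNA array than on the scrambled siRNA array by a ratio of 3.48.

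Mitosis and replication genes were lower on the TWIST1 siRNA array, with a mitosis median of -2.08 against scrambled siRNA. A difference in spike-in level is argued against by TWIST1 siRNA over control, where the poly-A ratio was 1.01 and the mitosis median -2.33. A scaling or intensity trend of the array is argued against by a median of -2.04 with that trend removed. An off-target effect of the siRNA and a difference between cultures cannot be told apart from an effect of TWIST1 targeting, since there was only 1 TWIST1 siRNA array. Lower proliferation after TWIST1 targeting therefore stays an open, untested hypothesis.

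Osteogenic, BMP, matrix and contractile genes were lower on the FGF2 array, which also had a lower spike-in level than the control array. For osteogenic and BMP genes the spike-in difference is argued against by FGF2 over scrambled siRNA, 2 arrays of like spike-in level, where the higher of both medians was -0.47 and below the range of random lists. That pair also differs in transfection and treatment time. Scrambled siRNA over control was itself above the range, at 0.12 for both lists, so part of the -0.47 can come from the scrambled siRNA array. The same holds for extracellular matrix genes, with a median of -0.18 there against -0.29 over control. Scrambled siRNA over control was at -0.16 for these genes, within the range, with 18 of 26 members below 0. A part of the matrix difference may thus go with spike-in level or handling. For contractile genes the median there was -0.13, below the range but much nearer to 0 than the -0.45 over control, and scrambled siRNA over control was itself at -0.28, so that a spike-in or handling difference and FGF2 cannot be told apart for this group. A response of matrix and osteogenic genes to FGF2 may account for the others, and a difference between cultures stays open with 1 array per group.

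TWIST1 was only slightly lower on the TWIST1 siRNA array, at -0.42. A signal close to background could narrow a larger difference: on all 4 arrays TWIST1 read within the range of the background control probe sets, 103 to 420, which met the condition first set for this explanation. A comparison with all genes was added after that, and 48.2% of them lay in the same range. The condition thus does not separate background from a weak but real signal. The -0.42 was also close to the robust SD of the differences of all genes in this comparison, 0.409. A partial knockdown, a compressed one and no knockdown therefore cannot be told apart. The long interval of the TWIST1 probe set leaves open which transcripts it reads.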

How the results depend on the processing

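The alternatives that set values under 100 to 100, and the lists and overlap with the control arrays exchanged, were chosen after the data were seen. No paired analysis was possible because each group had 1 array, its number was given in accession order, and no test was run.

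At 1.5-fold the counts higher and lower were 83 and 144 for FGF2 over control, 634 and 1106 for TWIST1 siRNA over scrambled siRNA, and 58 and 112 for scrambled siRNA over control, and at 3-fold they were 7 and 0, 19 and 156, and 0 and 0, as a smaller or larger limit must give. With the floor at the upper quartile, which by construction admits fewer genes, 12 genes were higher for FGF2, 67 higher and 242 lower for TWIST1 siRNA, and 2 higher and 8 lower for scrambled siRNA. With no floor 13 genes were higher for scrambled siRNA, and the overlap of FGF2 and TWIST1 siRNA grew from 10 genes to 19, while at 1.5-fold it was 66. The lower count for scrambled siRNA was 7 after quantile normalization and 8 with the intensity trend removed, where the cause was not tested. Over members at or above the floor alone, the number of lists outside the range for scrambled siRNA was 4 in place of 8, and the chondrogenic median for FGF2 turned from -0.27 to 0.15 with fewer members. Each other count that answers a comparison, 71 values in all, stayed within 1.5 times of its main value or, for TWIST1, close to it, at -0.38 for TWIST1 siRNA over scrambled siRNA under both rescalings. Of the list medians and single genes 479 alternative values moved little, 37 moved further and 1, that chondrogenic median, changed sign from a call. Of the 30 list calls, 29 were kept with each array minus its median, 26 with the trend removed, 29 with the mean of all probe sets, 28 with values under 100 set to 100 and 22 over members at or above the floor. Over those members the calls that ended were the chondrogenic and protease lists for FGF2, angiogenic and immunomodulatory factors for TWIST1 siRNA, and 4 lists for scrambled siRNA. With the trend removed they were the protease list for FGF2, immunomodulatory factors for TWIST1 siRNA, and the protease and BMP lists for scrambled siRNA. With values under 100 set to 100 they were the MSC surface and chondrogenic lists for FGF2, with each array minus its median immunomodulatory factors for TWIST1 siRNA, and with the mean of all probe sets the protease list for scrambled siRNA.

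Signal over background limits the dim genes: background control probe sets read up to 420, so differences of genes below that level, TWIST1 included, may be understated (-0.42 as deposited and -0.38 rescaled). The simulated noise for TWIST1 siRNA took the whole spread of that comparison (robust SD 0.409, against 0.206 for FGF2 over control), which also holds any real differences, so the 138 unchanged genes it called are no estimate of false calls.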

Other observations

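The histone and lysosomal lists below, the search of annotated processes and the count of shared splits were chosen after the leading genes were seen.

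Replication-dependent histone genes, which are transcribed while DNA is copied, were lower on the TWIST1 siRNA array. Over 32 genes the median log2 difference was -1.27 against scrambled siRNA, and 11 were at least 2-fold lower and bright enough for the rule. Others past 2-fold, such as HIST1H3B, which read 22 against 79, were too dim to be called. The exceptions were HIST1H2BN at 0.77, HIST2H2BE at 0.57 and HIST2H2BF at 0.44. On the FGF2 array the same genes had a median of 0.14 over control. Near-identical copies make the single values uncertain.

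Lysosomal genes were higher on the TWIST1 siRNA array. A list of 40 lysosomal genes was written after FUCA1 had been seen among the leading genes, leaving out FUCA1 and other lysosomal genes already seen, and before its own values were computed, to ask whether lysosomal genes were higher as a group. Over the 38 measured members the median was 0.50 against scrambled siRNA, above a random range of -0.21 to 0.11, and 35 were above 0. It was 0.45 against the untransfected control, again above the range, while for FGF2 over control it was -0.12. The protease CTSD differed by 1.23, TPP1 by 1.21, NAGLU by 1.16 and HEXA by 1.15, whereas PPT1 at -0.82 and GLA at -0.77 went the other way. A wider lysosomal programme on that array is therefore a candidate explanation for the place of FUCA1 among its leading genes, with no replicate to test it on.

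The medians of 1056 annotated processes were ranked, and the ends of each ranking are given with the range of random lists. For TWIST1 siRNA over scrambled siRNA the lowest was DNA strand elongation in replication at -1.24 over 31 genes (-0.24 to 0.13) and the highest lysosome organization at 0.41 over 24 genes (-0.20 to 0.18). For FGF2 over control the lowest was positive regulation of epithelial to mesenchymal transition at -0.36 over 17 genes (-0.14 to 0.09) and the highest sympathetic nervous system development at 0.18 over 17 genes (-0.13 to 0.12). For scrambled siRNA over control the lowest was positive regulation of endocytosis at -0.25 over 10 genes (-0.19 to 0.10) and the highest glycogen biosynthesis at 0.19 over 12 genes (-0.19 to 0.10). The 12 lowest processes for TWIST1 siRNA over scrambled siRNA all lay at -0.79 or lower, below all random lists drawn for each. The other ends lay nearer to their ranges, and the ends of so long a ranking can lie outside by selection alone, which was not tested.

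The arrays were split by spike-in level, FGF2 with scrambled siRNA against control with TWIST1 siRNA. This left 1 gene, PTMA, at least 2-fold apart on both arrays of each side. The dim other probe set of PTMA did not show this split. At 1.5-fold the split left 6 genes. PTMA, EEF1B2 and HIST1H3J were higher with FGF2 and scrambled siRNA, and FNDC1, FSTL3 and RNU5E-9P were lower. The split of FGF2 with TWIST1 siRNA against both controls left EGR1, RN5S26, PTPN22 and TRPC4. TRPC4 lay exactly 2-fold apart there, at 139 on the FGF2 array against 278 on the control array. The split of both siRNA arrays against the others left 1 gene, IFI44L. These genes were named after their values were seen.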
